A study of Oryza sativa Japonica Group with 5 samples.

How the data were processed

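Single-cell RNA-seq libraries of rice (Oryza sativa, Japonica Group) were analysed in 3 groups. S1 and S2 were young inflorescences, the organs that later form the panicle, and each had 2 libraries. S1 inflorescences were shorter than 2 mm and S2 inflorescences were 2 to 3 mm long. The third group was 1 library of the young flag leaf that encloses the inflorescence, which the submitters took as a control because bracts stay attached to the dissected organ. About 100 organs were pooled for each library. Per the labels' protocols, tissue was chopped and digested with cellulase and macerozyme, and the released protoplasts were loaded on the BD Rhapsody system, which captures single cells in microwells with barcoded beads. The labels number the replicates but do not say whether they came from separate plants or harvests, so p-values measure only the spread between these libraries, part of which may be technical.

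The deposited values were whole-number counts per gene and cell, 1 table per library, with no normalization found in the values. Per the submitters' processing notes, CASAVA 1.8, Cell Ranger and Seurat were used with the genome build IRGSP-1.0. The role of each tool, the annotation, the rule that called cells and the treatment of molecular identifiers are not given in the sources used here, so values are called counts and not molecules. The deposited tables listed 30614 identifiers over all libraries, of which 30241 began with Os. The reference gene table given for this organism (39387 genes) matched 1 of them, and the deposited tables do not pair identifiers with gene names. Gene names, the gene lists and the cell type markers fixed before the data were examined were therefore not used. Clusters are numbered, and genes are given by identifier only. Counting can split reads between near-identical gene copies, and this could not be checked.

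Barcodes with at least 500 counts and 200 detected genes were kept, which left 31676 of 37571 barcodes. The doublet caller scrublet (in scanpy 1.11.5, run per library) marked 2 cells, both in S1 replicate 1. A caller that marks under 0.5% of cells has not worked, so doublets remain in the data. The 2 cells were removed, leaving 31674 cells. An alternative that left out the 5% of cells with the most counts in each library was added after seeing the data.

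Counts were summed over the cells of each library, because cells are not replicates. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after TMM normalization and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. The S2 against S1 comparison used the 4 inflorescence libraries. The leaf comparison set the leaf library against the mean of S1 and S2 in a fit of all 5 libraries, and also required an absolute log2 fold change of at least 1. The lone leaf library was assumed to vary like the inflorescence libraries. Levels are CPM, counts scaled to a common library total, with TMM factors for single genes on library sums and without them where several genes were summed or levels are given per cluster. A fold against a library with 0 counts was computed against a floor of 3 counts in that library.

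For clustering, counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were selected across libraries, and 30 principal components and 15 neighbours were passed to the Leiden algorithm (igraph 0.11.9, resolution 1.0, 2 iterations), with all 5 libraries together and no integration. Clusters were numbered by size. The assignment of cells to clusters changed with the seed of the algorithm and with rounding in the arithmetic of the processor, so threads and processor instructions were fixed and seed 0 was kept as set before the data were examined. Seeds 1 to 10 were added as alternatives after seeing the data. Within each cluster with at least 50 cells in every inflorescence library, count sums were tested between stages as above. Shares of cells were tested with edgeR on cell counts, with library totals as sizes, for clusters with at least 50 inflorescence cells. Because the genes that differ between stages can define clusters, shares were also tested after clustering without those genes. The planned test of a meristem class against other cells could not be run without named markers. In its place, and chosen after seeing the data, each cluster was set against all other cells with a term for the difference of the stage effects, blocked by library. For the leaf library, shares are given with exact (Clopper-Pearson) 95% binomial intervals. These intervals, and the limit that 0 counts allow, cover counting error only.

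The planned rule for named genes took the largest fold changes among genes past the threshold with a mean of at least 20 CPM and no overlap between the groups' libraries, provided that a name was known. Since no names were paired, the 2 top genes of that rule without its name requirement are given for the rise in S2, and the 2 top genes for the fall in leaf.

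Each step was tested on simulated counts with known changes. Changed genes were drawn only from those at 20 CPM or more for library sums, and only from more abundant genes for clusters. The recovery given holds for such genes, and recovery of rarer genes was not tested. For S2 against S1 (20983 genes), 63% of genes changed 2-fold and 100% of genes changed 4-fold were recovered, with 8 false calls. For the leaf comparison (22585 genes), the shares were 48% and 100%, with 9 false calls. Within cluster 1 (9346 genes), 78% and 100% were recovered with 8 false calls, and within cluster 17 (8891 genes) 33% and 94% with 1 false call. For the difference of stage effects in cluster 1 (18772 genes), 61.5% of 4-fold differences were recovered with 6 false calls. All these gene counts were drawn with the trend of the dispersion alone, without the scatter of single genes around it. Recovery in the real data can therefore be lower, also for 4-fold changes. A cluster raised 4-fold in S2 was called in 19 of 20 simulated sets, with 2 false calls in 340 tests of unchanged clusters. These sets raised cluster 1 only, at a dispersion set by hand and not estimated from the shares. Recovery in the real data can therefore be lower.

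Alternatives fixed before the data were examined were DESeq2 1.42.0, other size factors, no filter on low counts, every barcode, a minimum of 1000 counts per cell, called doublets kept, each inflorescence replicate left out, the replicate number as a block, Leiden resolutions of 0.5 and 1.5, centring within libraries, and, for the shares of single clusters, clustering without the called genes. A fit with 1 inflorescence replicate left out assumes that the lone library of that stage varies like the libraries of the other stage. Clustering without the 3477 genes at an unadjusted p under 0.05, and clustering of the cells with at least 1000 counts, thinned to 1000, were added after seeing the data.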

Results

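Transcript counts were obtained from single protoplasts of young rice inflorescences at 2 lengths and of the young flag leaf around them. The lengths span the period in which branch, spikelet and floret meristems begin to form. S1 (under 2 mm) and S2 (2 to 3 mm) had 2 libraries each, and the flag leaf had 1. The S1 libraries held 31309950 and 26975254 counts in 7361 and 6488 barcodes, and the S2 libraries held 18581659 and 44897504 counts in 6631 and 9349 barcodes. The leaf library held 37817666 counts in 7742 barcodes. S2 replicate 1 was the shallowest, with a median of 713 counts per barcode, against medians from 1783.5 to 2188.5 in the other libraries. After filtering, 6702 and 5457 S1 cells, 4448 and 8547 S2 cells and 6520 leaf cells remained.

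The first question was how far flag leaf cells, taken as a control for bract tissue, differed from inflorescence cells. The cells formed 19 clusters, and leaf cells stood largely apart from inflorescence cells. Leaf cells made up over 50% of 4 clusters. Cluster 5 was 97.4% leaf, cluster 6 was 98.6% leaf, cluster 16 was 75.4% leaf and cluster 18 was 80.5% leaf. Together these clusters held 88.3% of the leaf cells (95% interval 87.5 to 89.1). They held 1.61% and 1.58% of the cells of the S1 libraries and 2.32% and 1.33% of the cells of the S2 libraries. Clusters 7, 9 and 19 were shared, with 5.44%, 15.2% and 34.4% leaf cells, and in each of the remaining 12 clusters leaf cells were under 5%. The borders of the clusters moved with the seed of the algorithm (adjusted Rand index of 0.523 to 0.683 between the main clustering and 10 other seeds), while the share of leaf cells in clusters over 50% leaf stayed between 86.6% and 89.7% over these seeds. With 1 leaf library and no integration, a cluster made mostly of leaf cells may be that library rather than a cell type.

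**Figure D1:**
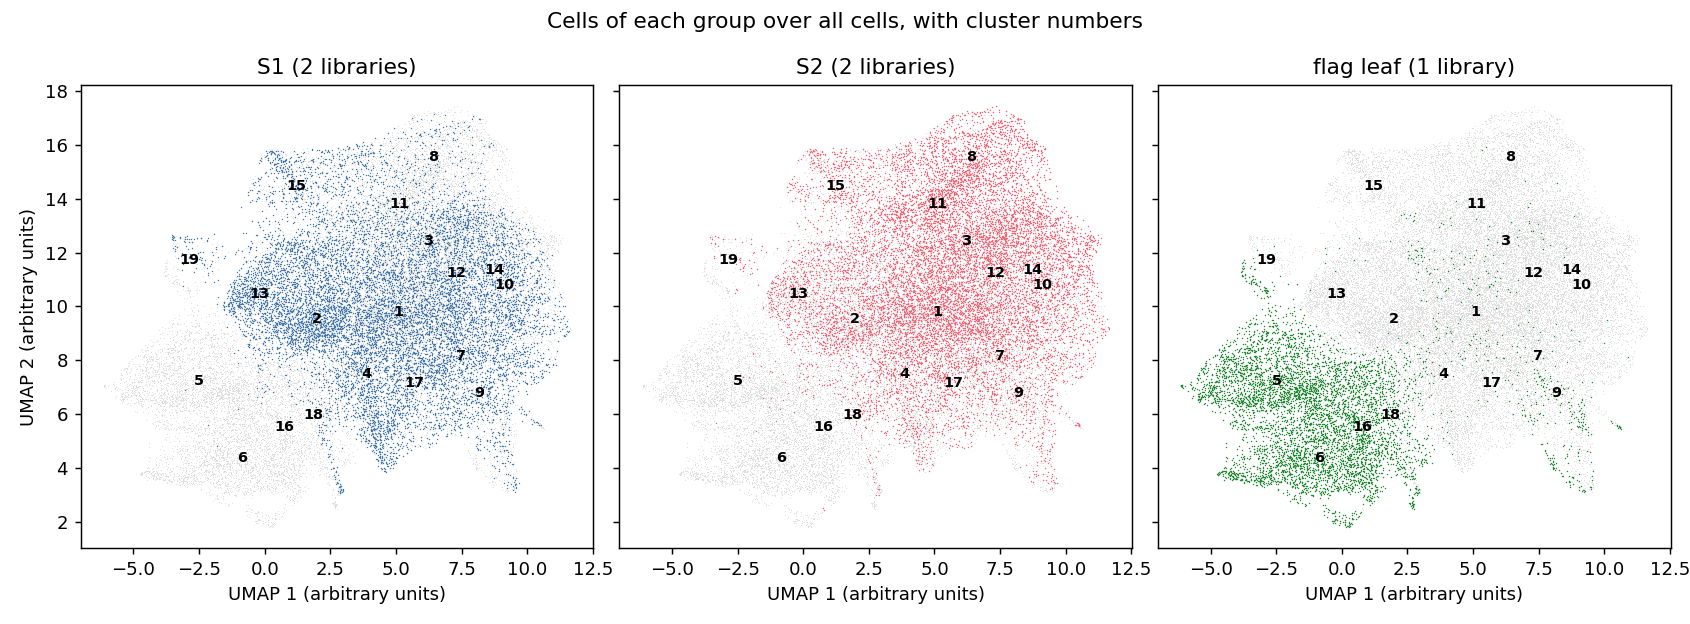
Cells of S1, S2 and flag leaf on the first and second UMAP axes (arbitrary units), each group coloured over all other cells in grey, with cluster numbers at the cluster medians. Leaf cells fill clusters 5, 6, 16 and 18, which held 88.3% of them, and S1 cells are sparse around clusters 8 and 11, where S2 cells are dense.

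Leaf and inflorescence also differed in many genes. Of 23181 genes tested on library sums, 2423 were higher and 2125 lower in leaf than in the mean of S1 and S2 (4548 in all). The difference was at least 4-fold for 1226 of the higher genes and 905 of the lower ones. Os03g0215400 had 0 counts in leaf and 108 ± 34.3 CPM in the inflorescence libraries (mean ± SD, n = 4). Os07g0129700 had 0 counts in leaf and 30.5 ± 1.64 CPM in the inflorescence libraries (mean ± SD, n = 4). Against the floor of 3 counts in the leaf library (0.0806 CPM), Os03g0215400 was at least 1337-fold lower in leaf and Os07g0129700 at least 379-fold lower. Both had an adjusted p of 0.000208 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They were the 2 genes with no count in leaf among the 6544 tested genes at 20 CPM or more in every inflorescence library. The single leaf library has no replicate, so its spread was taken from the inflorescence libraries.

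The comparison of S2 with S1 asked what changes as the inflorescence grows past 2 mm. Shares of cells differed in some clusters. Cluster 8 held 2.46% and 3.74% of the cells of the S1 libraries and 8.25% and 11.7% of the cells of the S2 libraries. Cluster 11 held 2.00% and 1.96% in S1 and 12.8% and 8.49% in S2. Cluster 14 held 1.92% and 2.53% in S1 and 4.07% and 7.80% in S2. Leaf cells were nearly absent from these clusters, which together held 0.245% of the leaf library. Cluster 11 was made of shallow cells (median 782 counts) and cluster 8 of deep ones (median 8146 counts). Taken as one, which was decided after seeing the data, clusters 8, 11 and 14 held 6.39% and 8.23% of S1 cells and 25.1% and 28.0% of S2 cells, a log2 ratio of 1.86 ± 0.37 (SE).

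Genes that differ between the stages could define these clusters, so cells were clustered again without the 9 genes called between stages. Of the 16 clusters tested there, with none picked for its overlap with clusters 8, 11 and 14, 1 was higher in S2. Its log2 ratio was 1.86 ± 0.35 (SE), with an adjusted p of 0.0368 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That cluster was the closest match of cluster 11 (Jaccard index 0.588), and the closest matches of clusters 8 and 14 were not higher past the threshold. With cells clustered without the 3477 genes at an unadjusted p under 0.05, 0 of 15 clusters passed the threshold in edgeR and 4 had an unadjusted p under 0.05. The cluster there with the lowest p, which held 32.1% of the cells of clusters 8, 11 and 14, had a log2 ratio of 1.23 ± 0.21 (SE) and an adjusted p of 0.0729 in edgeR. The cluster there made up mostly of these cells (57.4%) had a log2 ratio of 0.61 ± 0.31 (SE) and an adjusted p of 0.279 in edgeR. The rise of clusters 8, 11 and 14 as one in the main clustering missed the threshold without S1 replicate 1 (log2 ratio 1.69, adjusted p of 0.226 in edgeR) and without S1 replicate 2 (log2 ratio 2.06, adjusted p of 0.294 in edgeR). With each of 10 other seeds at least 1 cluster was higher in S2 past the threshold, in tests of all clusters of that seed.

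**Figure D2:**
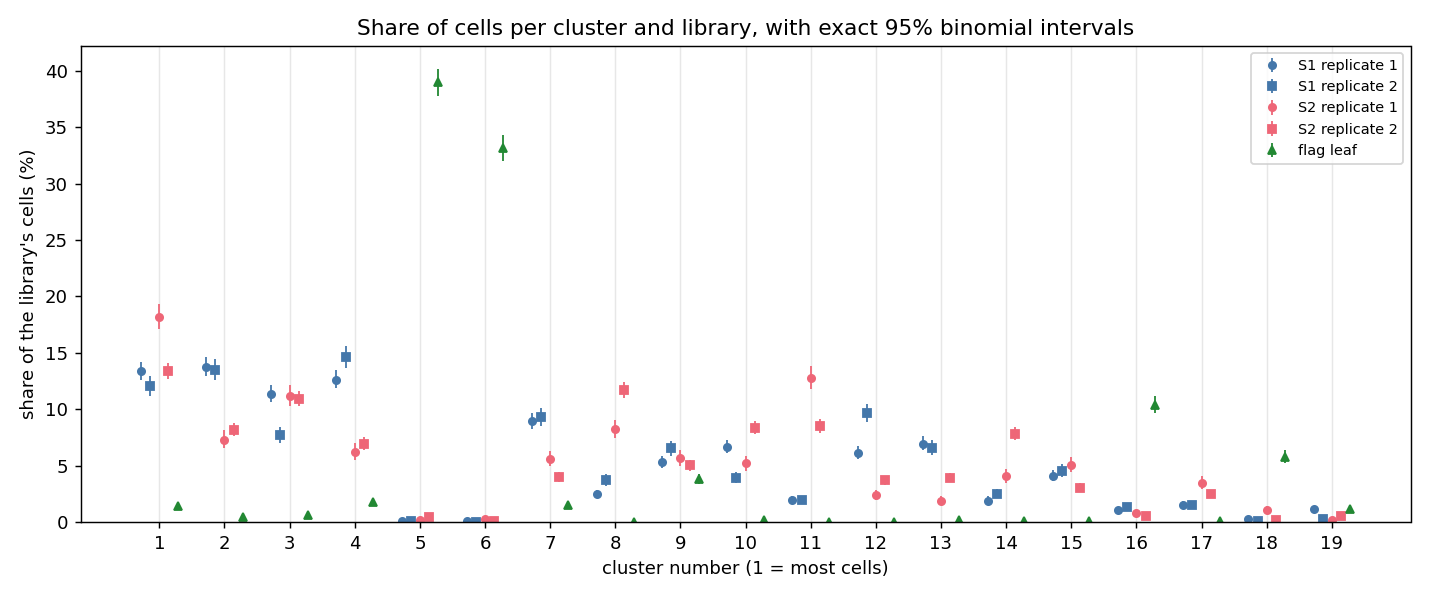
Share of each library's cells (%) in each of the 19 clusters, with exact 95% binomial intervals that cover counting error only. Both S2 libraries lie above both S1 libraries in clusters 1, 5, 6, 8, 11, 14 and 17 and below both in clusters 2, 4, 7, 12, 13 and 16. Of these, 8, 11, 12 and 14 passed the threshold, and cluster 6 was not tested. Clusters 5, 6, 16 and 18 hold mostly leaf cells. Shares within a library add up to a whole, so a rise in some clusters lowers others.

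Cluster 12 was the 1 cluster past the threshold that was lower in S2. It held 6.13% and 9.64% of S1 cells and 2.41% and 3.71% of S2 cells, a log2 ratio of -1.36 ± 0.45 (SE) with an adjusted p of 0.0333 in edgeR. With 1 inflorescence library left out its adjusted p in edgeR ran from 0.0581 to 0.406, so the call was lost in all 4 cases. Without the 9 called genes the closest cluster, which matched cluster 12 poorly (Jaccard index 0.255), was also lower in S2, with a log2 ratio of -1.61 ± 0.34 (SE) and an adjusted p of 0.0368 in edgeR. The closest clusters with seeds 5, 6 and 8 were lower past the threshold, and those with the other 7 seeds were lower without passing it. The direction was lost at resolution 0.5 (log2 ratio 0.07, Jaccard index 0.159, adjusted p of 0.827 in edgeR) and without the 3477 genes (0.13, Jaccard index 0.213, adjusted p of 0.901 in edgeR). Of 18 clusters tested one at a time, 4 passed the threshold in edgeR. The count was 0 without S1 replicate 1 and 0 without S1 replicate 2, with 3 clusters at an unadjusted p under 0.05 in each case, and it was 2 without S2 replicate 2. DESeq2 was not run on the cell counts.

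On library sums, 9 of 21282 genes differed between S2 and S1, and all 9 were higher in S2, by log2 fold changes from 1.51 to 2.77. Os12g0555500 rose from 57.4 ± 4.93 CPM in S1 to 393 ± 92.5 CPM in S2 (mean ± SD, n = 2 and 2), a log2 fold change of 2.77 ± 0.20 (SE) with an adjusted p of 0.0448 in edgeR. Os12g0555000 rose from 138 ± 13.2 CPM in S1 to 690 ± 53.6 CPM in S2, a log2 fold change of 2.32 ± 0.15 (SE) with an adjusted p of 0.0408 in edgeR. Their identifiers are close to each other, and reads shared between similar copies could not be excluded. Libraries of the stages did not overlap for any of the 9 genes. Of all genes tested, 50.7% did not overlap, against 33.3% by chance for 2 libraries against 2 if the libraries vary alike. The S2 pair lay farther apart than the S1 pair, which raises the share that chance gives. The excess is therefore no measure of a stage effect.

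This count of genes, and its split by direction, changed with the libraries in the fit and with the tool. In edgeR it was 0 without S1 replicate 1 (1389 genes at an unadjusted p under 0.05) and 0 without S1 replicate 2 (1179 such genes), 3732 without S2 replicate 1 (2203 higher and 1529 lower in S2) and 2878 without S2 replicate 2 (1267 higher and 1611 lower). In each of these fits 1 stage keeps a single library, which is assumed to vary like the pair of the other stage. The S1 pair was the closer one (SD of log2 differences 0.180, against 0.358 for the S2 pair, over 3157 genes). The counts with an S2 library left out therefore rest on the spread of the S1 pair alone, and they do not separate the effect of a library from that of the smaller spread. The same holds for every other value given here with a replicate left out. DESeq2, run on all 4 libraries, called 703 genes (507 higher and 196 lower), the 9 among them. In edgeR the count was 29 with library totals, 1403 with no filter on low counts (861 higher and 542 lower), 2 with at least 1000 counts per cell, and 0 without the 5% of cells with the most counts (2733 genes at an unadjusted p under 0.05; DESeq2 was not run there).

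The 9 genes together reached 363 and 368 CPM in the S1 libraries and 1543 and 1682 in the S2 libraries. They were most abundant, among inflorescence cells, in clusters 8, 11 and 14, which held more S2 cells. Their summed level was 2154 and 2057 CPM in cluster 8 of the S1 libraries, and 4009 and 3682 in cluster 8 of the S2 libraries. In cluster 11 it was 2035 and 1952 in S1 and 3247 and 3537 in S2. In cluster 14 it went from 951 and 963 in S1 to 3036 and 3339 in S2. Both S2 libraries lay above both S1 libraries in 13 of the 14 clusters tested, a count to which choosing the genes for being higher in S2 contributes. That choice also favours genes abundant in clusters with more S2 cells.

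**Figure D3:**
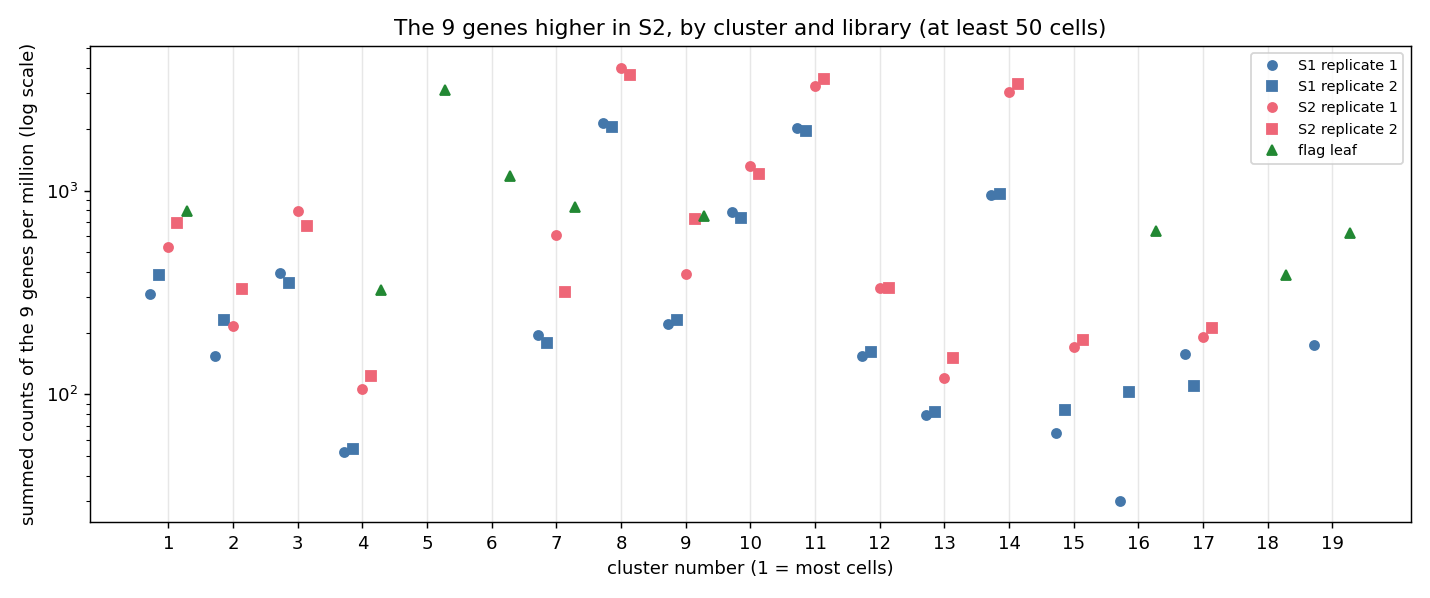
Summed level of the 9 genes higher in S2, in CPM on a log scale, for each cluster and library with at least 50 cells in that cluster. S2 libraries reach 3036 to 4009 CPM in clusters 8, 11 and 14, and the leaf library reaches 3104 in cluster 5.

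Within clusters, stage differences were called in 1 of the 14 clusters with enough cells in every inflorescence library. Cluster 14 had 21 genes higher and 6 lower in S2, with log2 fold changes from -2.63 to 5.44, and 4 of these 27 genes were among the 9 called on library sums. In each of the other 13 clusters edgeR called 0 genes, while 328 to 1109 genes had an unadjusted p under 0.05, and DESeq2 made 29 calls over these clusters. The calls in cluster 14 fell to 4 without S1 replicate 1 and to 0 without S1 replicate 2 (edgeR, 708 genes at an unadjusted p under 0.05; DESeq2 was run on all 4 libraries only, with 66 calls in this cluster), and rose to 538 without S2 replicate 1 and 464 without S2 replicate 2. Because the borders of clusters moved with the seed, so did the count over clusters, from 0 to 23 genes over 10 other seeds (0 for seeds 1 and 6 in edgeR, with 321 to 1766 and 247 to 1059 genes per cluster at an unadjusted p under 0.05; DESeq2 was not run on these). Over all clusters it was 1194 without S2 replicate 1, 2503 without S2 replicate 2, 36 without S1 replicate 2 and 42 without S1 replicate 1, where 33 calls were in cluster 17.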

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

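Chosen only after the result was seen were the tests of the stage effect in each cluster against other cells and of the calls it keeps, of thinned cells, of the cells with the most counts, of the 3477 genes at an unadjusted p under 0.05 and of the spread left once cluster shares are subtracted, and the bounds for the planned clustering without the 9 called genes.

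The stage effect of some genes differed between a cluster and all other cells, by a test of the difference itself. The number of such genes was 97 in cluster 1, 52 in cluster 2, 91 in cluster 3, 28 in cluster 4, 1 in cluster 7, 45 in cluster 8, 75 in cluster 9, 315 in cluster 10, 6 in cluster 11, 358 in cluster 12, 87 in cluster 13, 465 in cluster 14, 54 in cluster 15 and 240 in cluster 17. Simulated counts for cluster 1, drawn without the scatter of single genes, gave 6 false calls, and the other clusters were not simulated for this test. Over the 11 clusters other than 8, 11 and 14 there were 1398 differences, from 369 without S1 replicate 1 and 581 without S1 replicate 2 to 2886 without S2 replicate 2 and 3432 without S2 replicate 1. In each of these fits 1 stage keeps 1 library and is assumed to vary like the other, so an effect of the library left out is not separated from the smaller spread of the S1 pair.

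Because clusters 8, 11 and 14 held more cells in S2, their genes could be raised in the other cells of S2 and lower the S2 against S1 ratio of a cluster set against them, as in 1140 of the 1398 differences. With those clusters left out of the other cells, 5.94% of the differences kept their call, under the 50% set as the bound for this source, and clusters 1, 2, 3, 4, 7 and 15 had 0 left (edgeR; DESeq2 was not run there). The sizes shrank less: the median difference kept 59.96% of its log2 size (quartiles 41.8% and 76.4%), with median sizes of 0.98 before and 0.56 after (median SE 0.21 and 0.22), and 1378 of 1397 kept their sign. That percentage lies between the bounds of 50% and 75% set beforehand. The make-up of the other cells and a different effect of stage in these clusters therefore cannot be told apart.

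The larger share of clusters 8, 11 and 14 in S2 could reflect depth, since cluster 11 is shallow and S2 replicate 1 is the shallowest library. Only the 22238 cells with at least 1000 counts could be thinned to 1000, which left out most cells of cluster 11 (median 782 counts). Of the 15 clusters tested there, none picked by overlap, 1 was higher in S2 past the threshold. Its log2 ratio was 2.46 ± 0.39 (SE). It was the closest match of cluster 8 (Jaccard index 0.495) and a poor match of cluster 11 (0.151). For cells of that depth this argues against depth as the whole source, and for shallower cells depth was not tested. In the clustering without the 9 called genes 1 cluster rose past the threshold, by 1.86. It was the closest match of cluster 11 (Jaccard index 0.588). The closest matches of clusters 8 (0.446) and 14 (0.279) were not higher past the threshold. The clusters there picked as mostly cells of clusters 8, 11 and 14 rose together by 1.52 ± 0.24 (SE). These rises argue against the 9 genes as the whole source, for a single cluster only in the match of cluster 11. In thinned cells the cluster past the threshold was instead the closest match of cluster 8. Without the 5% of cells with the most counts the log2 ratio of mean shares was 1.90, no lower than the 1.86 with all cells. Leaving out 5% of cells cannot undo shares of 25.1% and 28.0% in S2. The bound set for doublets was thus out of reach, and this test cannot decide on them. Doublets among other cells also stay open and untested. Whether the many weaker stage differences define these clusters cannot be told apart from a population that expands: without the 3477 genes at an unadjusted p under 0.05 the cluster made up mostly of the same cells (57.4%) rose by 0.61 ± 0.31 (SE) on the log2 scale and the cluster with the lowest p by 1.23 ± 0.21 (SE), neither past the threshold, and leaving out so many genes also removes those that would mark such cells. An expanding population stays open as a hypothesis, with the stage as the biological difference that the design names. The shares are of released protoplasts that passed the filter, so shares of cells in the tissue were not measured.

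The S2 replicates differed from each other nearly as much as from S1. Over 3157 genes, the SD of the log2 difference was 0.358 between the S2 replicates, 0.180 between the S1 replicates and 0.369 to 0.404 between libraries of different stages. With all libraries thinned to the lowest total the SD between the S1 replicates was 0.183. The lower total of S2 replicate 1 thus added little counting noise for these genes. They were chosen for high levels in every inflorescence library, so thinning could hardly raise the SD, and other effects of depth were not tested. In cells of at least 1000 counts the SD between the S2 replicates was 0.363, so the spread was also there in deeper cells. Cells under 1000 counts hold a small part of the sums, so leaving them out could hardly lower the SD. That test therefore cannot decide on shallow cells as a source. Subtracting the difference that cluster shares predict brought S2 replicate 2 to 0.225 and 0.232 from the S1 libraries but left the S2 replicates 0.330 apart, which argues against the shares of these clusters as the whole source. S2 replicate 1 then lay 0.286 and 0.332 from the S1 libraries, farther than S2 replicate 2. A difference in its length or condition stays open and was not tested.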

How the results depend on the processing

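Alternatives chosen after seeing the data were those without the 5% of cells with the most counts, without genes at an unadjusted p under 0.05, with cells thinned to 1000 counts and with Leiden seeds 1 to 10, clustering without the called genes for the genes within clusters, and all alternatives for the leaf share, for clusters 8, 11 and 14 as one and for the difference of stage effects. The 9 genes between S2 and S1 stayed within 1.5 times in number with RLE size factors, every barcode, doublets kept and all 5 libraries in the fit. The number was 703 with DESeq2 (507 higher, 196 lower), 29 with library totals, 1403 with no filter on low counts (861 higher, 542 lower), 2 with at least 1000 counts per cell, 0 to 3732 with single replicates left out (where a lone library is assumed to vary like the other stage), and 0 without the 5% of cells with the most counts (edgeR, 2733 genes at an unadjusted p under 0.05; DESeq2 was not run there). With no filter edgeR's median prior degrees of freedom was 36.9 against 4.05, and 7 of the 1403 genes lay outside those tested with the filter. Both genes named for S2 kept their direction in the alternatives run, with adjusted p-values up to 0.227, and missed the threshold without S1 replicate 1, without S1 replicate 2, without the 5% of cells with the most counts and, for Os12g0555500, with at least 1000 counts per cell. The replicate number as a block gave 57 genes on library sums, 161 within clusters and a log2 ratio of 1.87 for clusters 8, 11 and 14 as one, which missed the threshold; the numbers do not pair the libraries (correlation of deviations 0.00569 across genes). The 4548 genes of the leaf comparison stayed within 1.5 times in all 14 alternatives (3190 to 6058 with single replicates left out), and DESeq2 called 3896 of them in the same direction. The 27 genes within clusters became 84 with DESeq2, 36 to 2503 with single replicates left out, 0 at resolution 0.5 (edgeR, 370 to 1223 genes per cluster at an unadjusted p under 0.05; DESeq2 was not run there), 7 with centring, 5 with doublets kept, 2 without the called genes and 5 in thinned cells, and for seeds 1 to 10 they became 0, 3, 23, 3, 2, 0, 9, 2, 1 and 14. The 4 clusters with a changed share became 0 to 4 with single replicates left out, 2 at resolution 1.5, 7 with centring, 2 with doublets kept, 2 without the called genes, 0 without genes at an unadjusted p under 0.05 (edgeR, 4 clusters at an unadjusted p under 0.05) and 1 in thinned cells, and for seeds 1 to 10 they became 2, 1, 1, 2, 4, 3, 2, 8, 1 and 1. For clusters 8, 11 and 14 as one, other clusterings were read from the clusters made up mostly of the same cells, which were chosen for their rise, so the direction there was largely set in advance and says little about stability. Of the 22 alternatives 6 missed the threshold, with log2 ratios of 1.86 at resolution 1.5, 1.46 with seed 7, 0.61 without genes at an unadjusted p under 0.05, 1.69 and 2.06 without either S1 replicate, and the block; single replicates left out gave 1.69 to 2.06. The leaf share of 88.3% was 83.4% at resolution 0.5, 85.8% at resolution 1.5, 83.1% with centring, 89.7% with doublets kept, 78.5% without genes at an unadjusted p under 0.05, 84.6% in thinned cells, and 87.2%, 89.7%, 87.2%, 86.6% and 89.5% with seeds 3, 4, 6, 9 and 10. The 1398 differences of stage effect became 88 without the clusters that grew among the other cells and 369 to 3432 with single replicates left out; seeds were not run for these. Clusters themselves were not stable (adjusted Rand index of 0.523 to 0.683 over the seeds), and keeping doublets adds 2 cells only, so a value of a single cluster holds for this clustering alone. Apart from that, the cause of these changes was not tested. Not run, because no names were paired, were the gene list tests, the meristem class test and the co-detection test with its thinning alternatives. In simulated counts 33% of 2-fold changes were recovered in cluster 17, so small changes in such clusters can be missed. Larger changes can be missed too, since neither the scatter of single genes nor changes in rarer genes were simulated.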

Other observations

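The tests of leaf material, cluster shares, neighbouring identifiers and shared labels were chosen only after the results were seen. The 9 genes higher in S2 also had high levels in the flag leaf. Their summed level was 1886 CPM in the leaf library, against 363 and 368 in S1, and 8 of the 9 were higher in leaf than in both S1 libraries. Among clusters made up mostly of leaf cells, leaf cells reached 3104 CPM in cluster 5 and 1182 in cluster 6. They reached 630 CPM in cluster 16 and 384 in cluster 18. The few leaf cells of clusters 3 (42 cells) and 14 (10 cells) had higher levels, at 9212 and 5221 CPM. In all other clusters leaf cells lay below the level of cluster 5. In the leaf comparison 4 of the 9 passed the threshold as higher in leaf and 1 as lower.

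Leaf cells or leaf RNA in the S2 libraries could raise such genes. A mixture cannot exceed its parts, and 4 of the 9 genes were higher in both S2 libraries than in leaf and in both S1 libraries. This argues against leaf material with the average make-up of the leaf library as the whole source. Leaf cells of cluster 5 were above that average for the summed genes, at 3104 CPM, and the few leaf cells of clusters 3 and 14 were higher still. Leaf material of another make-up is therefore not covered. To reach the summed S2 level, 82.0% of the S2 counts would have to come from leaf material of the average make-up. The 52 other genes at 100 CPM or more in leaf and at least 4 times the level of either S1 library would then have a median log2 fold change of 2.65. They had 0.63 (quartiles 0.07 and 1.16), with 0 of the 52 reaching the level needed. This too argues against leaf material of the average make-up as the whole source. A first pair of bounds on this median, 0.5 and 1, had decided nothing, and the other measures were chosen after that. Clusters over 95% leaf held 0.239% and 0.147% of S1 cells and 0.450% and 0.632% of S2 cells, higher in both S2 libraries, so leaf material as a small part of the rise stays open. Why the median of the 52 lay above 0 was not tested.

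The rise of the 9 genes may come in part from the larger share of clusters 8, 11 and 14. In S2 these clusters held 80.2% and 79.6% of the counts of the 9 genes, against 44.6% and 53.3% in S1. The change of cluster shares accounted for 50.1% to 55.1% of the rise over the 4 pairs of an S1 and an S2 library in the main clustering, and for 38.6% to 40.6% in the clustering without the 9 genes, with higher levels within clusters for the rest. These values lie on both sides of the 50% set as the bound, so the clusterings do not decide which part is larger. Genes with more counts weigh more in this sum. What raised the levels counted within clusters was not tested.

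Genes with neighbouring identifiers changed together. Across 21208 genes, which are not independent replicates, the log2 fold changes of S2 against S1 had a correlation of 0.107 between neighbours in identifier order on the same chromosome, 0.0451 at 2 places apart and -0.0110 at 50 places apart. The highest correlation in 1000 shuffles of the order within chromosomes was 0.0220. For leaf against inflorescence the values were 0.168, 0.0694 and 0.00466 over 23059 genes, and the highest shuffled value was 0.0231. Reads shared between adjacent copies and shared regulation were not separated.

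Cell labels found in more than 1 library gave no sign of molecules carried between libraries. Over the 10 pairs of libraries 448 labels were shared, 0.803 times the 558 that chance gives, a level chosen after a first one was tried, for labels built from 97, 98 and 106 common sections. The pairs with S2 replicate 1 lay furthest below chance, at 33, 26, 38 and 35 labels against 48.4, 42.7, 61.5 and 50.9. Why they did was not tested. Only barcodes in the deposited tables were compared, so carry-over at low levels would not show. Of the 369 shared labels whose cells were clustered in both libraries, 17 fell in the same cluster, against 18.4 by chance.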
